A study of Drosophila melanogaster with 2 samples.

How the data were processed

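The series measured binding of Stat92E, the transcription factor of the Drosophila JAK/STAT pathway, by ChIP-seq in whole embryos aged 0 to 12 h, of mixed sex. Per the labels, the flies carried Stat92E with a C-terminal eGFP tag, the precipitation was made against GFP, and chromatin was sonicated to fragments of 200 to 800 bp. The antibody label names Stat92E while the protocol text names GFP, and this difference stays open. There was 1 group with 2 biological replicates, numbered 1 and 3 in the labels. No untreated or second group was analysed here, and no control sample was analysed here, so every comparison is made within the peak lists against the genome, against neighbouring sequence or against other genes.

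The authors called peaks on genome build dm6, per the file lists that came with the samples. These lists state that each replicate list came from that replicate's alignments and a control shared by both, that a pooled list came from both replicates together, and that a further list was thresholded by IDR (the irreproducible discovery rate) from the replicate lists and the pooled list. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here. The signal of each deposited peak is a score of the authors' peak caller with no stated unit, and it was used to rank peaks within a list, to describe single peaks, and for a rank correlation of the replicates across shared peaks. The deposited -log10 q-value took 1 shared value, 3.62, in all 3603 peaks of the IDR-thresholded list, so it could not rank them. The other deposited column used was the summit position. Each replicate list and the pooled list held exactly 30000 peaks, so list length carries no information about the number of binding sites. Peak width took 1 value in 98.5% of the peaks of replicate 1, 98.8% of those of replicate 3 and 97.2% of pooled peaks, so widths were not compared. Read depth is unknown, because the lists hold no read counts.

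The IDR-thresholded list is called the reproducible set below. All of its 3603 peaks were identical to the 3603 strongest peaks of the pooled list. The name is a label for this list and does not state that each peak was found in both replicates. On the arms, 99.0% of its peaks had a peak in both replicate lists, and replicate 3 had 0 peaks on the mitochondrial chromosome. The set held 2 peaks on the mitochondrial chromosome, which were left out of all comparisons. The remaining 3601 peaks lay on 6 chromosome arms (2L, 2R, 3L, 3R, 4 and X). Gene models came from Ensembl release BDGP6.54.115 and sequence from the RefSeq copy of Release 6, the assembly of dm6, and every peak ended inside its chromosome. Each summit was assigned to the protein-coding gene with the nearest transcription start site (TSS) among 13945 genes, which names a neighbour and not a regulated gene. The gene lists held 300 entries, of which 295 matched a symbol of the annotation used; the others were left out, and peaks near genes missing from the annotation went to their neighbours.

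Replicate overlap was taken between the 3603 strongest peaks of each replicate with a minimum of 1 bp, against 100 random placements on the same arms. Summits within 1 kb of a protein-coding TSS were called promoter peaks. Their share was compared with the share of arm bases by a two-sided exact binomial test and with 1000 random placements. Other summits were classed as exon, intron or intergenic in that order. The share of peaks on X and peaks within 500 bp of a tRNA gene were tested in the same ways. Motifs were searched on both strands in the 101 bp centred on each summit and in a control window 1 kb to one side, chosen by a seeded coin. The 26 motifs formed 1 family, with exact McNemar tests and Benjamini-Hochberg adjustment. Ratios of shares carry 95% intervals from 2000 bootstrap draws over peaks, and shares carry 95% exact binomial intervals. All 8192 distinct 7-mers were tested likewise with Bonferroni adjustment. The relation of signal to motif was tested with 100000 permutations, two-sided. For 19 gene lists, the number of members with an assigned peak was compared with 10000 random lists matched on territory length, the stretch in which a summit is assigned to the gene, in 20 bins (two-sided permutation test, Benjamini-Hochberg over the lists). Peaks and genes are not biological replicates, so these p-values describe the peak set of 2 replicates and not variation among embryos. Intervals cover counting error only.

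Motifs, gene lists, tests and the rule for named genes were fixed before the data were examined. The rule named the genes of the 20 strongest peaks, all members of the JAK/STAT component and described-target lists, up to 4 members with the strongest peak of each other list, and the genes of the 5 strongest peaks with TTCCNGGAA within 50 bp of the summit. Alternatives changed the window sizes, the control sequences, the gene assignment, the matching and the peak set, including the stricter 50% of peaks by signal and each replicate alone. Leaving out a replicate meant taking the 3603 strongest peaks of the remaining one. A further 6 alternatives were chosen after seeing the data: the weakest peaks of the pooled list as comparison for the promoter share and for the motif, 1 peak per interval, ranking by the signal of 1 replicate, and another random seed for the gene lists and for the control windows. The seed used in a first exploration differed from the final one, and its results are given as the last of these.

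The tests were tested on simulated data. With a full STAT palindrome planted in 200 of 3601 genomic windows, the 3-base-spacer motif was recovered (adjusted p = 2.68e-20, exact McNemar test) and 3 of 3 planted 7-mers were called. Without planting, 1 of 26 motifs and 0 of 8192 7-mers were called. For gene lists of 15 members, 2.5% of 200 unchanged lists reached an unadjusted p under 0.05. At the same unadjusted threshold, lists with 50% of members hit were recovered in 66% of 50 simulations, and those with 70% in 100%. A list of this size with a smaller excess could therefore be missed. Recovery after adjustment over the 19 lists, which the calls below required, was not simulated and can be lower. The simulated members were hit independently of each other. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.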

Results

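Stat92E-GFP occupancy was mapped in 0 to 12 h embryos in 2 biological replicates. The series title states no aim beyond profiling a transcription factor in the whole organism, and the comparisons below ask where the factor lay, next to which genes and on which sequences. The reproducible set held 3603 peaks, which merged into 3383 separate regions. The 3601 peaks on the chromosome arms covered 1479053 bp. Signal scores in this set ranged on the arms up to 1084.85, with a median of 160 and a minimum of 121 over all its peaks.

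Most of the strongest peaks of the replicates overlapped. Of the 3586 arm peaks among the 3603 strongest of replicate 1, 2443 (68.1%) overlapped one of the 3603 strongest of replicate 3, against a mean of 2.33% for random placements (permutation p = 0.0099, the smallest that 100 placements allow). With 50% reciprocal overlap the share was 60.5%, and with summits within 100 bp it was 53.6%. It was 64.7% for the 1801 strongest peaks of each list and 73.0% for the 7206 strongest. The random placements covered whole arms, so they do not allow for a shared location at promoters. Of the reproducible peaks on the arms, 99.0% had a peak in both replicate lists and 66.1% were among the 3603 strongest of both. The set was derived from these same lists, so these shares are not independent evidence of agreement. The replicate lists also reached down to a -log10 q-value of 0.331 (replicate 1) and 0.447 (replicate 3). Across 3564 of the reproducible peaks the signal in replicate 1 and replicate 3 was correlated with a Spearman rho of 0.454. This correlation is across peaks, which are not independent replicates, and the set equals the strongest peaks of the pooled list, so it was chosen by pooled signal.

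**Figure D1:**
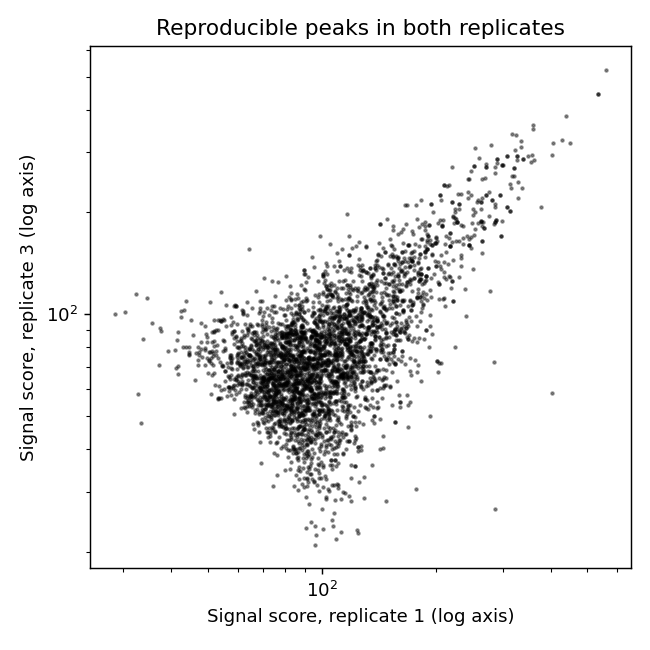
Signal score of each of 3564 reproducible peaks in replicate 1 (horizontal, log axis) and replicate 3 (vertical, log axis), 1 point per peak. The points rise together with wide scatter (Spearman rho 0.454).

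The strongest arm peaks included those of the receptor of the pathway, the transcription factor itself and its feedback inhibitor. The peak with the highest signal on the arms (1084.85) lay in plexus (px) on 2R at 22514112 to 22514519, 206 bp from a TSS. The next (973) lay at the promoter of domeless (dome), the JAK/STAT receptor, on X at 19682985 to 19683638. The peak of Socs36E, which encodes a suppressor of cytokine signalling, ranked 13 in the reproducible set, and that of Stat92E ranked 16. The remaining peaks among the 20 strongest were assigned to cbt, CG31668, CG18549, CycB, Art3, Chro, Lk6, CG5953, gish, CG14100, CG11050, Ppa, Rac2, Reg-2, shn and chif. All 20 were among the 100 strongest peaks of both replicates, 13 were promoter peaks, and 10 held a TTCNNNGAA site within 50 bp of the summit. The assigned genes are neighbours: the summit assigned to Reg-2 lay 16099 bp upstream of its TSS, and that assigned to CycB, a mitotic cyclin, lay 3324 bp away beyond the end of the gene.

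Sites in these peaks were sought only within 50 bp of the summit, so the distances below have that limit by construction. In dome, TTCCTGGAA lay on X at 19683246 to 19683254, 4 bp from the summit, and TTCTCGGAA lay at 19683220 to 19683228. In Stat92E, TTCCAGGAA lay on 3R at 20550408 to 20550416, 34 bp from the summit and inside the gene. The same sequence lay under the peaks of Ppa on 2R (22689868 to 22689876) and of Reg-2 on 3L (622653 to 622661). In Socs36E, TTCTCAGAA lay on 2L at 18151716 to 18151724, 16 bp from the summit. The peaks of dome, Stat92E, Ppa, Reg-2 and RhoU were the 5 strongest with the full palindrome TTCCNGGAA. The RhoU peak ranked 80 and lay in an intron on X at 10115594 to 10115945.

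Among 13 JAK/STAT components and regulators, 8 had a reproducible peak against 2.61 expected for matched random lists, a ratio of 3.06 (adjusted p = 0.0114, permutation test). These were dome, Stat92E, Socs36E, Ptp61F, ken, Su(var)2-10 and the ligand genes upd2 and upd3. Socs36E had 6 assigned peaks and dome had 3. Peaks were counted by summit, and the dome peaks of ranks 4 and 47 shared 1 interval. Of the 16 peaks of this list, 11 (68.8%, interval 41.3 to 89.0) held a 3- or 4-base-spacer site at the summit, against 14.8% of all 3601 peaks. The interval treats peaks as independent, although 4 of the 11 were assigned to Socs36E and 2 to dome. The 14.8% was not matched on location: 50% of the 16 were promoter peaks, against 65.5% of all peaks. Among all peaks, 24.7% of those away from promoters and 9.58% of promoter peaks held such a site. No reproducible peak was assigned to upd1, hop, et, Socs44A or Socs16D. Their strongest assigned peaks ranked 6011, 8347, 19939, 4234 and 3698 in the pooled list. The ligand gene peaks were weak: upd3 ranked 3506, with rank 1016 in replicate 3 and 11479 in replicate 1. The replicates also differed for ken (rank 598 in replicate 3 and 5691 in replicate 1) and Su(var)2-10 (7078 and 2266). The excess missed the threshold with the stricter 50% of peaks (ratio 3.51, adjusted p = 0.0621, permutation test) and with both other rules of gene assignment. Here and for every list below, the random lists were not matched on expression in embryos. Ribosomal protein genes gave a larger ratio (4.06) and Notch pathway genes a similar one, so such an excess was not particular to this pathway.

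Of 31 genes described as JAK/STAT targets, 22 had a reproducible peak against 8.65 expected (ratio 2.54, adjusted p = 0.0019, permutation test). Of their 70 peaks, 28.6% (interval 18.4 to 40.6) held a 3- or 4-base-spacer site. Only 32.9% of the 70 were promoter peaks, against 65.5% of all peaks. Among all peaks, 24.7% of those away from promoters and 9.58% of promoter peaks held such a site. The interval includes the 24.7%, so no excess of sites beyond location is shown for these genes. Of the 22 genes with a peak, dome, Stat92E, Socs36E and ken also belong to the component list, so their peaks count in both. Diap1, an inhibitor of apoptosis, had 5 peaks, and the strongest, of rank 162, held no 3- or 4-base-spacer site at the summit. TTCCGGGAA lay under the Diap1 peak of rank 1137, on 3L at 16044278 to 16044286. ImpL2 also had 5 peaks, and its strongest (rank 105) held no such site. The Diap1 peaks of ranks 162, 213 and 1137 shared 1 interval, as did the ImpL2 peaks of ranks 105 and 561. In the posterior spiracle gene cv-c, TTCCTGGAA lay on 3R at 14482317 to 14482325, upstream of the gene. The genes crb, vvl, fj, chinmo, slbo, zfh1, Mmp1, pnt, apt, eya, Antp, Sxl, Tep2, wg and trh had peaks too, from rank 321 for fj to rank 3070 for trh. Some ranks differed between replicates, as for the strongest peaks of wg (857 in replicate 3 and 12445 in replicate 1) and Antp (985 and 4867). The members without a reproducible peak were eve, run, kni, mirr, dpp, CycD, TotA, TotM and vir-1. The pair-rule gene eve had a strongest pooled peak of rank 24736, and none of the 30000 pooled peaks was assigned to CycD, TotA, TotM or vir-1. The excess missed the threshold when any summit within the gene or 5 kb of it was counted (ratio 1.44, adjusted p = 0.0828, permutation test).

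Peaks of Stat92E-GFP lay mainly at promoters. Of 3601 summits, 2358 (65.5%, interval 63.9 to 67.0) were within 1 kb of a protein-coding TSS, a stretch that takes 20.3% of the arms. Random placements gave a mean of 20.3% and at most 23.0% (permutation p = 0.001, the smallest that 1000 placements allow). Introns held 20.7% of summits against 36.3% of arm bases and intergenic sequence held 12.9% against 28.3%. Coding sequence outside promoters held 5 summits (0.139%), although it takes 10.8% of the arms. The promoter share was 66.6% in replicate 1 alone and 62.9% in replicate 3 alone. Among the 3603 weakest peaks of the pooled list, a set chosen after seeing the data, it was 28.6%. That list reached down to a -log10 q-value of 0.396, so its weakest entries have little statistical support as peaks.

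In the reproducible set the X chromosome carried fewer peaks than its length predicts, and tRNA genes carried more than random placements. X held 440 of 3601 peaks (12.2%, interval 11.2 to 13.3) and takes 17.6% of the arm length (exact binomial p = 1.12e-18). It was also below its share of protein-coding genes, 15.7% (exact binomial p = 2.25e-09). The expected shares did not allow for the number of X copies in embryos of mixed sex. The deficit differed with the signal cut: X held 10.1% of the stricter peaks by signal. In the whole pooled list, poorly supported peaks included, X held 219 peaks per Mb, within the range of 2L, 2R, 3L and 3R (216 to 237). In the reproducible set it held 18.7 per Mb against 27.2 to 30.1 on those arms. Arm 4 was lower than X in both lists (96.4 and 15.6 per Mb). Within 500 bp of the 290 annotated tRNA genes lay 59 summits, 1.64% of all, against a mean of 6.45 and a maximum of 15 for random placements (permutation p = 0.001). These summits lay near 94 of the tRNA genes. This comparison was planned as a technical check, because highly transcribed tRNA genes are a known site of unspecific ChIP signal. It cannot tell such signal from binding of the factor.

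STAT sites were enriched at the summits. The 3-base-spacer site TTCNNNGAA was present in 314 of 3601 summit windows (8.72%, interval 7.82 to 9.69) and in 110 control windows (3.05%). The ratio was 2.85 (interval 2.33 to 3.52; adjusted p = 1.31e-23, exact McNemar test). The full palindrome TTCCNGGAA was present in 45 summit and 8 control windows, a ratio of 5.63 (interval 2.87 to 16.7; adjusted p = 1.23e-06, exact McNemar test). The size of this ratio rests on few control windows: it was 21.5 (43 and 2 windows) with replicate 1 alone and 3.73 (41 and 11) with replicate 3 alone. The reversed half-sites GAANNNTTC gave a ratio of 1.27 (interval 0.991 to 1.65). In the weakest peaks of the pooled list the 3-base-spacer ratio was 0.966 (interval 0.746 to 1.27). These have little statistical support as peaks, since that list reached down to a -log10 q-value of 0.396.

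Promoter motifs of other factors were enriched as well. DRE, the TATCGATA element of the factor DREF, was in 104 summit and 12 control windows, a ratio of 8.67 (interval 5.17 to 19.2). This size also varied, with 33.7 (3 control windows) for replicate 1 alone and 10.9 (8 control windows) for replicate 3 alone. Core promoter motif 1 (YGGTCACACT) was in 77 and 3 windows, and the GAGA factor motif GAGAGAG was in 112 and 61, a ratio of 1.84. Control windows were not matched on distance to a TSS, so promoter elements can be enriched through the location of the summits alone. Away from promoters DRE was in 4 summit and 5 control windows and core promoter motif 1 in 2 and 2, a split chosen after seeing the data. The Snail motif CAGGTG was less frequent at summits, with 98 against 156 windows (ratio 0.628, adjusted p = 0.0011, exact McNemar test). This depletion was not seen against windows of equal GC content (ratio 0.891, adjusted p = 0.667, Fisher's exact test). Summit windows averaged 39.5% GC and control windows 43.4%. Motifs of Zelda, Su(H), GATA, Dorsal, Caudal, Runx, TEAD, AP-1, Ets, Bicoid, Grainyhead and the E-boxes did not pass the test, nor did the homeodomain motif and the CA repeat. Against windows of equal GC content, the E-boxes CACGTG (ratio 1.93) and CAGCTG (1.36) were higher and the Bicoid (0.696), Runx (0.681) and homeodomain (0.787) motifs lower, with adjusted p from 0.0132 to 0.0234 (Fisher's exact tests). The Runx motif was also lower with replicate 1 alone (ratio 0.628, adjusted p = 0.0070) and the Bicoid motif with replicate 3 alone (0.683, adjusted p = 0.0295, exact McNemar tests).

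**Figure D2:**
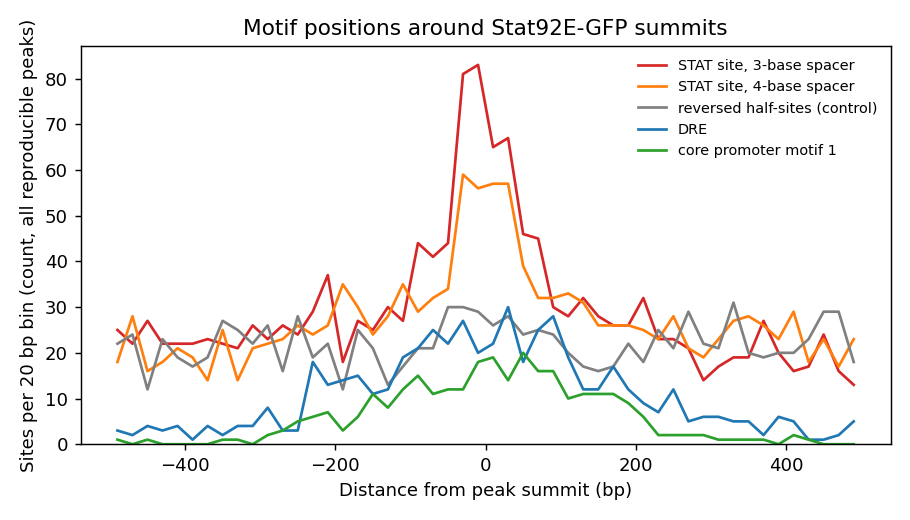
Number of motif sites per 20 bp bin (vertical) by distance from the summit in bp (horizontal), summed over 3601 reproducible peaks, 1 line per motif. Within 20 bp of the summit lay 151 sites with the 3-base spacer against 48.0 expected from the flanks, while DRE sites were spread over a wider stretch.

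Spacers of 3 and 4 bases gave the highest ratios. With 4 bases between the half-sites, 244 summit and 116 control windows held a site, a ratio of 2.10 (interval 1.71 to 2.62). The other 7 spacers from 0 to 8 bases gave ratios from 1.04 to 1.44. Of these, the intervals for 0 bases (1.06 to 1.71) and 1 base (1.10 to 1.90) also lay above 1, but not against windows of equal GC content (0.889 to 1.39 and 0.990 to 1.67). Without replicate 1 the interval for 0 bases reached below 1 (0.895 to 1.46) and that for 8 bases lay above it (1.16 to 2.04). With the stricter 50% of peaks the ratios for 0 bases (1.72, interval 1.24 to 2.47) and 7 bases (1.74, interval 1.15 to 2.70) exceeded 1.44.

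**Figure D3:**
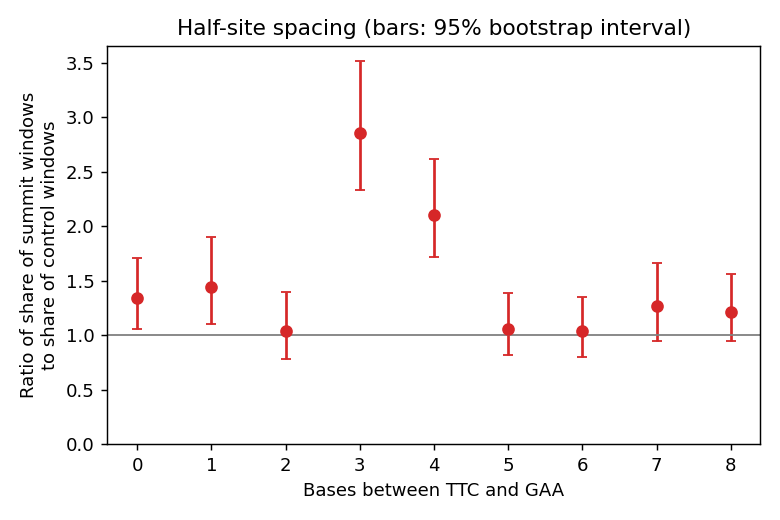
Ratio of the share of summit windows to that of control windows (vertical) holding TTC and GAA separated by 0 to 8 bases (horizontal), with 95% bootstrap intervals over 3601 peaks. The ratios for 3 bases (2.85) and 4 bases (2.10) lie above all others, the highest of which is 1.44.

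The strongest peaks held the 3-base-spacer site most often. In the strongest 20% of peaks, 125 of 721 summit windows (17.3%, interval 14.6 to 20.3) held it, against 8.89% in the next group of equal size and 5.42%, 5.69% and 6.25% in the following ones. Presence of the site rose with signal (Spearman rho 0.134 across peaks, permutation p = 1e-05, the smallest possible). The promoter share was 58.7% in the strongest group and 67.8% in the weakest.

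**Figure D4:**
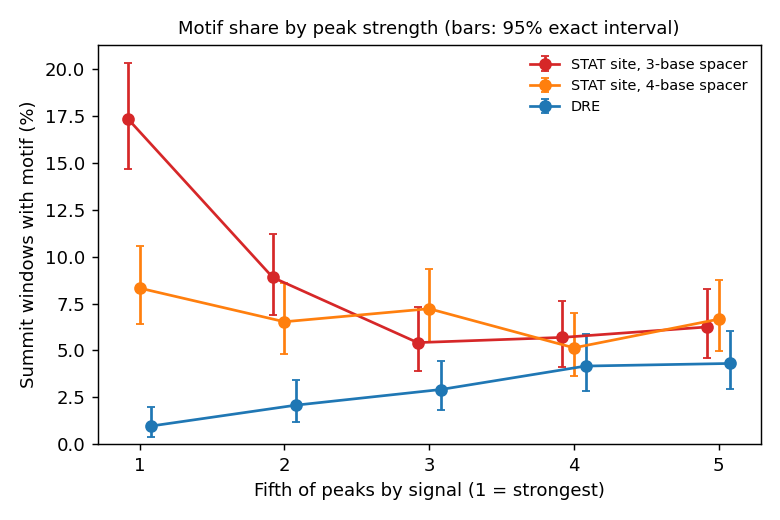
Percent of summit windows with a motif (vertical) in 5 groups of reproducible peaks ordered by signal (horizontal, 1 is strongest), with 95% exact binomial intervals. The 3-base-spacer site falls from 17.3% in the strongest group to 6.25% in the weakest, while DRE stands at 0.971% and 4.31%. With replicate 3 alone DRE stood at 3.47% in the fourth group and 2.22% in the weakest, so it did not rise throughout.

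Among 7-mers, 52 were enriched and 50 depleted at summits. The leading one was ATCGATA of the DRE element (228 summit and 50 control windows), followed by CTATCGA, and GGTCACA of core promoter motif 1 (128 and 26). The control windows were not matched on distance to a TSS here either. Of the 52 enriched 7-mers, 25 consisted of A and T alone. Against windows of equal GC content 37 were enriched, none of A and T alone, and 18 of these were shared with the 52. The depleted ones were led by CGAGGAG (12 and 86 windows). Against windows of equal GC content 12 were depleted, led by GCCAGGA (6 and 55), and CGAGGAG was not among them.

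In all, 2507 of 13945 protein-coding genes (18.0%) had an assigned peak, and 8 of 19 lists passed the threshold, all above expectation. Tracheal and posterior spiracle genes had peaks at 10 of 14 members (ratio 2.29, adjusted p = 0.0158, permutation test), led by cv-c (rank 227), grn, a GATA factor (296), ems (305) and crb (355). EGFR and FGF pathway genes had peaks at 12 of 17 (ratio 2.47, adjusted p = 0.0038, permutation test), among them Egfr (rank 188), the repressor gene aop with 7 peaks (199), aos (248) and spi (252). Of the members with peaks, cv-c, crb, vvl and trh of the tracheal list also belong to the described-target list, as does pnt of the EGFR and FGF list. The EGFR and FGF call was lost with summits within 1 kb of a TSS (ratio 1.81, adjusted p = 0.239) and within the gene or 5 kb of it (1.29, adjusted p = 0.488, permutation tests). The tracheal call was lost under the latter rule (1.46, adjusted p = 0.203, permutation test). Notch pathway genes had peaks at 9 of 15 (ratio 2.94, adjusted p = 0.0114, permutation test), led by E(spl)m7-HLH (rank 43), numb (496), E(spl)m3-HLH (674) and N itself (804). Most of these 9 were E(spl) genes, and E(spl)m3-HLH and E(spl)m7-HLH start close together on 3R (26021823 and 26037038). The random lists drew genes singly, so neighbouring genes counted as separate hits.

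Dorsal-ventral patterning genes had peaks at 10 of 18 members (ratio 2.12, adjusted p = 0.0394, permutation test), led by Doc3 (rank 91), pnr (495), ush with 7 peaks (547) and tup (1411). Doc1, Doc2 and Doc3 all had peaks and counted as separate hits. The dorsal-ventral call was lost with replicate 1 alone (ratio 1.78, adjusted p = 0.222, permutation test) and with the stricter 50% of peaks (1.74, adjusted p = 0.531). It was also lost with summits within 1 kb of a TSS (1.28, adjusted p = 0.758) and within the gene or 5 kb of it (1.13, adjusted p = 0.854, permutation tests). Cell cycle genes had peaks at 8 of 15 (ratio 2.68, adjusted p = 0.0255, permutation test), led by CycB (rank 8), E2f1 (136), dap (1075) and CycA (1107). With replicate 3 alone this excess had an adjusted p of 0.0727 and with replicate 1 alone one of 0.0636 (permutation tests). It was lost with the stricter peaks (adjusted p = 0.307) and with both other rules of assignment (0.195 and 0.0828, permutation tests).

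Ribosomal protein genes carried peaks more often than matched genes. Peaks were assigned to 14 of 22 members against 3.45 expected (ratio 4.06, adjusted p = 0.0019, permutation test), led by RpL14 (rank 300), RpL3 (310), RpL19 (409) and RpL11 (486). The ratio was 2.72 with summits within 1 kb of a TSS and 1.96 within the gene or 5 kb of it, both past the threshold. All 16 peaks of this list lay at promoters and 0 of 16 held a 3- or 4-base-spacer site at the summit (interval 0 to 20.6%), which includes the 9.58% of all promoter peaks. Heat shock genes had peaks at 6 of 14 (ratio 2.75) and lay next to the threshold (adjusted p = 0.0553, permutation test, and 0.0477 with another random seed). Their peaks were led by Hsp27 (rank 210), Hsp83 (552), Hsp68 (755) and Hsp26 (1485).

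**Figure D5:**
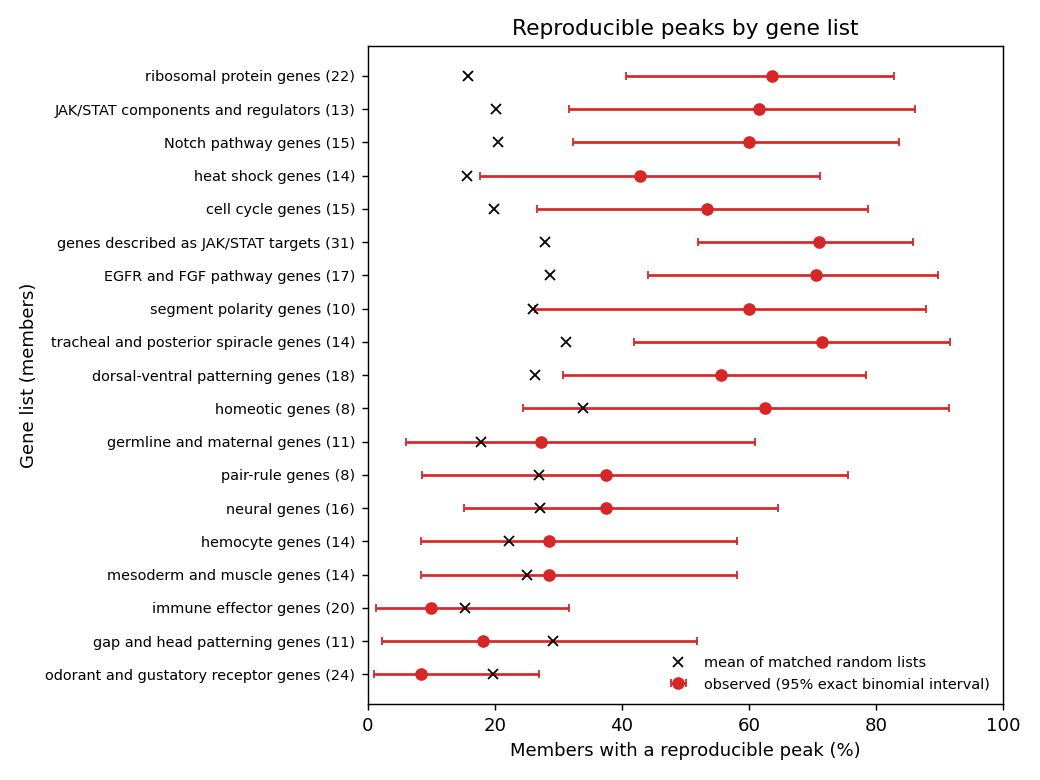
Percent of the members of each of 19 gene lists with a reproducible peak (points, with 95% exact binomial intervals) and the mean of matched random lists (crosses). Ribosomal protein genes reach 63.6% against 15.7% expected and odorant and gustatory receptor genes 8.33% against 19.6%.

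The other lists did not pass the test. Their directions were not stable: the ratios of the homeotic, hemocyte, mesoderm, pair-rule, neural, germline, gap and immune lists crossed 1 under at least 1 alternative. Segment polarity genes had peaks at 6 of 10 members (ratio 2.31, adjusted p = 0.0771, permutation test), among them ci (rank 114), ptc (232), nkd with 8 peaks (440) and gsb-n (1823). Homeotic genes had peaks at 5 of 8 (ratio 1.84, adjusted p = 0.303, permutation test), with Antp (1257), Dfd (1399), abd-A (2232) and Abd-B (3265) strongest, and at 0 of 8 with summits within 1 kb of a TSS. Pair-rule genes had peaks at 3 of 8 members in the annotation used, namely slp2 (118), slp1 (453) and opa (1613), and gap and head genes at 2 of 11, ems and oc. Neural genes had peaks at 6 of 16, including elav (51), grh (109), insc (632) and SoxN (1183). Mesoderm and muscle genes had peaks at 4 of 14 (tin, zfh1, Mef2 and bin), and hemocyte genes at 4 of 14 (ush, crq, Pvr and gcm2). Germline and maternal genes had peaks at 3 of 11 (bcd, piwi and stau). Immune effector genes had peaks at 2 of 20 (AttD and Tep2), a ratio of 0.654, which turned to 1.84 (10 of 20, adjusted p = 0.121, permutation test) when any summit within the gene or 5 kb of it was counted. Odorant and gustatory receptor genes had peaks at 2 of 24 (Gr93a and Or67d), a ratio of 0.425 with an adjusted p of 0.363 (permutation test).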

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

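For the patterns below, the test of the reversed half-sites was chosen only after its result was seen. Peaks on the mitochondrial chromosome stood out in data that no comparison used: replicate 1 had 17 of them, with a signal score of up to 23640 against at most 559 on its arms, and replicate 3 had 0. The 2 mitochondrial peaks of the reproducible set, between positions 1307 and 3180, had its highest signal, 23412, although replicate 3 had no peak there.

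The enrichment of STAT sites at summits was weighed against base composition. Against random windows of equal GC content the ratio of the 3-base-spacer site was 2.47, with an interval of 2.04 to 3.05, which argues against GC content as the whole cause. The reversed half-sites, with equal base content, gave 1.27, with an interval wholly below that of the site. A candidate explanation left by these tests is direct binding of a part of the peaks by the tagged factor, and the design has no second group that would test it.

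The concentration at promoters may come in part from signal that does not depend on STAT sites. Ribosomal protein genes, which are very highly transcribed, held peaks 4.06 times as often as matched genes, and 2.72 and 1.96 times under the rules of 1 kb from a TSS and of the gene or 5 kb, all above the 1.5 set beforehand for signal at highly transcribed genes. At promoter peaks a 3- or 4-base-spacer site was 1.78 times as frequent as in control windows (interval 1.46 to 2.21), between the bounds set beforehand for signal without sites and for binding at sites, so these cannot be told apart for promoter peaks as a set. Away from promoters the ratio was 3.23 (interval 2.63 to 4.06). The excess of summits at tRNA genes, 59 against a mean of 6.45, had no bounds set beforehand and was not weighed here. No expression data or second antibody was used here, and no biological explanation was tested.

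The neighbourhood of Stat92E could hold extra peaks if copies of the tagged construct raised the local signal. The 40 kb centred on the gene held 27 pooled peaks against a median of 12 for other protein-coding genes, and 93.5% of those genes had fewer. This lies between the bounds set beforehand, so extra copies and binding at this locus cannot be told apart. No biological explanation was tested for it.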

How the results depend on the processing

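The alternatives named in the methods as chosen after seeing the data are included here. Promoter share, X share, STAT sites, the 4-base spacer, the rise with signal, tRNA genes and replicate overlap kept direction and call under every alternative run. No call turned direction; for lists that never passed, direction was not scored. Replicates taken alone gave promoter shares of 62.9% and 66.6% and STAT ratios of 2.35 and 2.78. The stricter 50% held 1801 peaks, 1799 of them on the arms and used, with 23 enriched 7-mers and 5 lists past the threshold. Replicates alone gave 7 and 6 lists, no matching on territory gave 10, and another seed gave 9. Summits within 1 kb of a TSS gave 4 lists, losing JAK/STAT components (1.93), dorsal-ventral (1.28), EGFR and FGF (1.81) and cell cycle genes (1.91). Summits within the gene or 5 kb gave 2 lists, losing JAK/STAT components (1.67), described targets (1.44), dorsal-ventral (1.13), tracheal (1.46), EGFR and FGF (1.29) and cell cycle genes (1.69). The stricter peaks lost JAK/STAT components (3.51), dorsal-ventral (1.74) and cell cycle genes (2.46). Without matching, segment polarity (3.34) and homeotic genes (3.48) passed, as did heat shock genes with another seed (2.75, a ratio that the seed does not change). Single replicates gave cell cycle ratios of 2.37 to 2.43 and dorsal-ventral ratios of 1.78 to 2.49. The causes were not tested, though the stricter set has fewer peaks by construction. Of 110 named genes, 16 changed between peak and no peak in the stricter set, 10 with replicate 3 alone and 7 with replicate 1 alone. A lower IDR threshold was not run, because the list used gives no IDR value per peak, and ranking by pooled signal was not run, because it is the signal used. No paired analysis was possible because there is only 1 group. Read depth is unknown, so absence of a weak peak cannot be read as absence of binding.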

Other observations

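The values in this part come from tests chosen after seeing the data. Promoter peaks and the others differed in the motifs at their summits. The 3-base-spacer site was in 15.2% of 1243 summits away from promoters and in 5.30% of 2358 promoter summits (Fisher's exact p = 2.43e-22). The 4-base-spacer site was in 11.1% and 4.50% (Fisher's exact p = 4.50e-13). DRE went the other way, with 0.322% away from promoters and 4.24% at promoters (Fisher's exact p = 2.71e-14), and so did core promoter motif 1 with 0.161% and 3.18% (Fisher's exact p = 5.07e-12).

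Gene lists were also tested from each class of peaks alone, and the difference between classes was not itself tested. JAK/STAT components gave a ratio of 5.50 from peaks away from promoters and 2.89 from promoter peaks (adjusted p = 0.0123 and 0.0470, permutation tests). Described targets gave 3.62 and 2.73 (adjusted p = 0.0038 in both, permutation tests), and Notch pathway genes gave 4.71 and 2.83 (adjusted p = 0.0160 and 0.0470, permutation tests). Tracheal genes gave 2.99 and 2.85, and EGFR and FGF pathway genes 2.96 and 2.50, all past the threshold. Ribosomal protein genes (4.75), cell cycle genes (3.31, adjusted p = 0.0165) and heat shock genes (3.09, adjusted p = 0.0470, permutation tests) passed from promoter peaks and not from the others, where at most 1.01 members of each were expected.

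The 3-base-spacer and 4-base-spacer sites were each compared with signal. The Spearman rho with signal across peaks was 0.134 for 3 bases and 0.0232 for 4 bases (permutation p = 0.165), and the difference between the sites was not tested. DRE had a rho of -0.0724 (permutation p = 1e-05, the smallest possible). The genes with the most assigned peaks were Reg-2, pyd and shn, with 9 each, followed by Btk, Raf, nkd and tara with 8 each; pyd, Btk, Raf and tara fall outside the rule for named genes and were chosen after their values were seen.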
